A study of Mus musculus with 4 samples.

How the data were processed

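MicroRNAs (miRNAs) were measured on 4 microarrays, 1 for each combination of sample type (esophagus or serum) and age (28 or 46 weeks) of L2-IL-1β mice, a transgenic model of Barrett's esophagus. Per the labels' protocols, total RNA including small RNA was extracted with a mirVana kit from tissue and an miRNeasy Serum/Plasma kit from serum, then labelled with the dye Hy5 for Toray 3D-Gene arrays, which read 1 colour. How many mice contributed to each RNA sample was not given in the sources used here. The 2 kits differ between esophagus and serum, so kit and sample type cannot be told apart.

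The deposited scanner files held, per the file headers, the median intensity of each spot and the median intensity around it (the local background), in arbitrary linear units, with readings at 3 scanner gains joined by a fitted line. These intensities were neither background-corrected nor normalized. Scanner and software versions were not given in the sources used here. Each array had 3200 spots, of which 1265 were mouse miRNA probes, each spotted at 1 place, and 13 of these probes were shared by several miRNAs. A further 1664 spots were named BLANK and 97 No Probe. The authors' deposited value table held processed intensities on a linear scale. Set against the scanner values, each of its columns was the spot intensity minus a level within 0.05 of the BLANK mean, times 1 factor per array that put the median of the listed miRNAs at 25, with the largest departure from that line 0.0515 table units. It listed 1062 and 1035 miRNAs in esophagus at 28 and 46 weeks and 1068 and 943 in serum. The rule that left out the other miRNAs was not stated.

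Spot intensities were background-corrected with the normexp method of limma 3.58.1 in R 4.3.3, with the local background and an offset of 50. Control spots were then left out, values were taken to log2, and arrays were quantile-normalized within each sample type for the comparisons of age and over all 4 arrays for esophagus against serum. The offset draws differences of dim miRNAs toward 0. A miRNA was called detected on an array when its spot intensity was above the BLANK mean plus 2 SD, which lay at 57.5 and 60.4 in esophagus at 28 and 46 weeks and at 48.5 and 56.2 in serum. This limit is lenient, because it was also passed by 77.3% of No Probe spots on the esophagus array at 28 weeks and by 39.2% to 40.2% on the other arrays. A spot the scanner had marked as bad, that of miR-3109-5p in esophagus at 28 weeks, was left out there. Tables were handled and figures drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9, and jsonlite 2.0.0 was used in R.

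With 1 array per group there was no test and no p-value. Differences of log2 values were counted when they reached 2-fold between ages or 4-fold between sample types, over miRNAs detected on all arrays compared. Those detected at 1 age only were counted apart and are given with their net signal (spot intensity minus the BLANK mean) and no fold of their own, because a fold on the scale with the offset is no lower bound for such dim miRNAs. Where the authors' table listed such a miRNA at both ages, its difference there is quoted. The number of arrays limits the precision. A spot-noise SD beside a difference combines the SD of No Probe spots with the coefficient of variation of spike-in spots on each array, carried through the log2 values. It leaves out the error of the local background reading and all variation between mice, extractions and hybridisations. For changes in both sample types, the count was set beside n1 × n2 / N for independent lists.

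Lists of miRNAs were fixed before the data were examined, as were the design, the naming rule and all alternatives not described here as added. The 20 lists were the epithelial miR-200 family, squamous epithelium, columnar and glandular epithelium, smooth muscle, striated muscle, inflammation and leukocytes, erythrocytes, hepatocytes, fibroblasts and stroma, endothelium, neurons, pancreatic acinar cells, the let-7 family, the miR-17-92 and paralogous clusters, the miR-34 and miR-449 family, the miR-30 family, miRNAs reported in Barrett progression, the Dlk1-Dio3 imprinted cluster, the Sfmbt2 cluster families, and names numbered 1000 or more. For each list the median difference over detected members was placed among the medians of 10000 random lists of the same size drawn within 10 bins of mean level (seed 1). The percentile describes these arrays and is not a test. Older array names were matched for miR-142, miR-126 and miR-486, and the probe for miR-486-5p also reads miR-3107-5p.

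The miRNAs named were, for each age comparison, the 10 largest increases and 10 largest decreases of at least 2-fold among those detected on both arrays and at or above the median of detected miRNAs on at least 1 of them. Of miRNAs detected at 1 age only, the 3 brightest per direction were named. For changes in both sample types, and for esophagus against serum, the 8 per direction with the largest smaller difference were named, together with any member of the lists. Others are named as chosen after their values were seen.

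The 9 alternative settings fixed beforehand were scaling to the median, quantile normalization over the other sets of arrays, subtraction of the BLANK mean with quantile normalization, an offset of 16, the authors' value table, no detection filter, the brighter miRNAs only, and thresholds of 1.5-fold and 3-fold (2-fold and 8-fold between sample types). Another 3 were added after seeing the data: normexp without the local background, subtraction of the BLANK mean with scaling to the median, and detection above the No Probe mean plus 2 SD. The first of these was added because the local background was raised beside bright spots. Its median beside miRNA spots with a net signal of at least 500 was 227 and 167 in esophagus at 28 and 46 weeks and 244 and 307 in serum, against 49.0, 49.3, 39.7 and 46.4 beside undetected miRNAs, and it reached 93.0% of the spot intensity in esophagus at 28 weeks.

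The count of 2-fold differences was tested on simulated data with 200 changed miRNAs in each comparison of ages. Over 843 miRNAs of esophagus, 75.0% of bright miRNAs (net signal of at least 50) with a true log2 difference of 1.5 were recovered and 96.4% of those at 2, against 0% and 5.56% of dimmer ones, and 4 of 643 unchanged miRNAs were called. Without the local background, 83.3% and 96.4% of bright miRNAs were recovered and none of the 643 was called. Over 822 miRNAs of serum, 58.8% and 87.5% of bright miRNAs were recovered, against 0% and 3.95% of dimmer ones, and 4 of 622 unchanged miRNAs were called. In serum without the local background, 44.1% and 91.7% of bright miRNAs were recovered and none of the 622 was called. Because each group had 1 array, variation between mice, extractions and hybridisations could not be measured. The calls among unchanged simulated miRNAs therefore give no false-call rate for the measured comparisons. The list percentile was tried on the measured serum values, not on simulated data. With 1 log2 unit added at 46 weeks, 20 of 20 random lists of 6 members lay above the 97.5th percentile. Their members were drawn from all detected serum miRNAs, and shorter lists of bright miRNAs, whose random medians spread more widely, were not tried. Of the unshifted lists, 19 of 20 lay below it, which follows from drawing them from the same miRNAs as the random lists.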

Results

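MiRNA profiles of esophageal tissue and serum were compared between 28 and 46 weeks of age in L2-IL-1β mice, which express human interleukin-1β in the esophagus and develop inflammation and Barrett's esophagus, the replacement of the squamous lining by columnar epithelium. The series asks which miRNAs change in tissue and in serum as the disease advances. Each of the 4 groups was represented by 1 array, so there were no replicates and none of the differences below has a replicate check. All 4 samples carry the disease label of Barrett's esophagus, and no mice without the transgene and no younger mice were analysed here.

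Of 1265 miRNA probes, 973 (76.9%) and 939 (74.2%) were detected in esophagus at 28 and 46 weeks, and 1000 (79.1%) and 853 (67.4%) in serum. Most lay close to background. The median net signal of detected miRNAs was between 11.4 and 14.5 units, and 573, 678, 764 and 589 miRNAs in the same order were above the stricter limit set by spots without probe. A few miRNAs carried most of the signal. In esophagus, miR-3968 and miR-5100 took 18.1% and 14.4% of the net signal at 28 weeks and 17.5% and 12.99% at 46 weeks. In serum, miR-5100 took 13.7% and 16.2%, and miR-451a, the main miRNA of erythrocytes, took 11.1% at 28 weeks and 7.83% at 46 weeks. Across the 731 miRNAs detected on all arrays, log2 net signals at the 2 ages had a Pearson correlation of 0.98 in esophagus and 0.97 in serum, against 0.82 to 0.85 between esophagus and serum. These correlations are across miRNAs, which are not independent replicates.

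In esophagus, miR-144-3p, an erythroid miRNA made from the same primary transcript as miR-451a, fell between 28 and 46 weeks, and its spot intensity went from 135 to 64.4. Its log2 difference was -1.09 (spot-noise SD 0.06), or -1.19 without the local background, and -3.59 in the authors' deposited value table. The spot at 46 weeks lay just above the limit of 64.0 set there by spots without probe, so the size of the last value is not reliable. It was the one miRNA of this comparison whose 2-fold difference remained with and without the local background. Of 843 miRNAs detected at both ages, 4 were at least 2-fold higher at 46 weeks and 2 were at least 2-fold lower. The log2 difference was 2.51 for miR-203-3p, which promotes differentiation of squamous epithelium, 1.18 for miR-125b-5p, 1.13 for miR-1a-3p of striated muscle, 1.01 for miR-15b-5p and -1.15 for let-7a-5p.

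The differences of these other 5 esophageal miRNAs followed the local background more than the spots. The spot intensity of miR-203-3p was 1692 at 28 weeks and 2002 at 46 weeks, while the intensity around it was 1574 and 969.8. For miR-1a-3p the spot read 3074 and 3637 and its surroundings 2039.8 and 766, and for miR-125b-5p the spot read 864 and 922 and its surroundings 607 and 54.9. For let-7a-5p the spot read 1383 and 1459 and its surroundings 293 and 889. When the local background was not used, their log2 differences were -0.14 for miR-203-3p, -0.16 for miR-125b-5p, 0.06 for miR-1a-3p, -0.13 for miR-15b-5p and -0.05 for let-7a-5p, and the counts became 0 higher and 1 lower. With the BLANK mean subtracted the counts were 12 and 14, the authors' table gave 11 and 13, and scaling to the median gave 4 and 1.

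Among the lists of cell-type miRNAs, the squamous pair miR-203-3p and miR-205-5p had a median of 1.37 in esophagus (99.5th percentile of random lists), with 1 of 2 members past 2-fold, and a median of -0.07 (34.1st percentile) without the local background. None of the 5 columnar and glandular miRNAs reached 2-fold. Their median was 0.14 (95.5th percentile), with miR-192-5p at 0.14, miR-194-5p at 0.19, miR-215-5p at 0.16 and miR-375-3p at -0.10. The epithelial miR-200 family had a median of 0.10 (85.9th percentile) and the smooth muscle list, with miR-143-3p at -0.91 (-0.18 without the local background) and miR-145a-5p at -0.31, had a median of -0.24 (4.88th percentile), or -0.18 (2.495th percentile) without the local background. In the let-7 family 1 of 9 members passed 2-fold. Its median was -0.30 (0.62nd percentile), and -0.11 (7.37th percentile) without the local background. The erythrocyte list had 1 of 4 detected members, miR-144-3p, past 2-fold and a median of -0.24 (2.36th percentile), with miR-451a at -0.18 and miR-16-5p at -0.31, and its median without the local background was -0.10 (10.5th percentile). No member of the inflammation and leukocyte list reached 2-fold (median -0.05, 37.6th percentile), among them miR-21a-5p at -0.07, miR-146a-5p at -0.26 and miR-155-5p at -0.14. Of the 14 detected miRNAs reported in Barrett progression, miR-203-3p alone passed 2-fold (median -0.04, 31.9th percentile), and miR-196a-5p and miR-196b-5p were not detected in esophagus at either age.

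The liver miRNA miR-122-5p was dim in esophagus, with a spot intensity of 74.9 at 28 weeks and 164 at 46 weeks, and a log2 difference of 0.69. It was 0.98 without the local background, 2.12 with the BLANK mean subtracted and scaling to the median, and 2.11 in the authors' table. A further 96 esophageal miRNAs were detected at 46 weeks only and 130 at 28 weeks only. The brightest of them were dim, with net signals of 11.9, 10.4 and 10.3 for miR-703, miR-3109-3p and miR-16-1-3p at 46 weeks, and 11.4, 10.9 and 10.7 for miR-3475, miR-6237 and miR-130c at 28 weeks. The authors' table, which lists some miRNAs under the detection limit used here, gave log2 differences of 1.36 for miR-16-1-3p, -1.71 for miR-6237 and -1.93 for miR-130c.

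**Figure D1:**
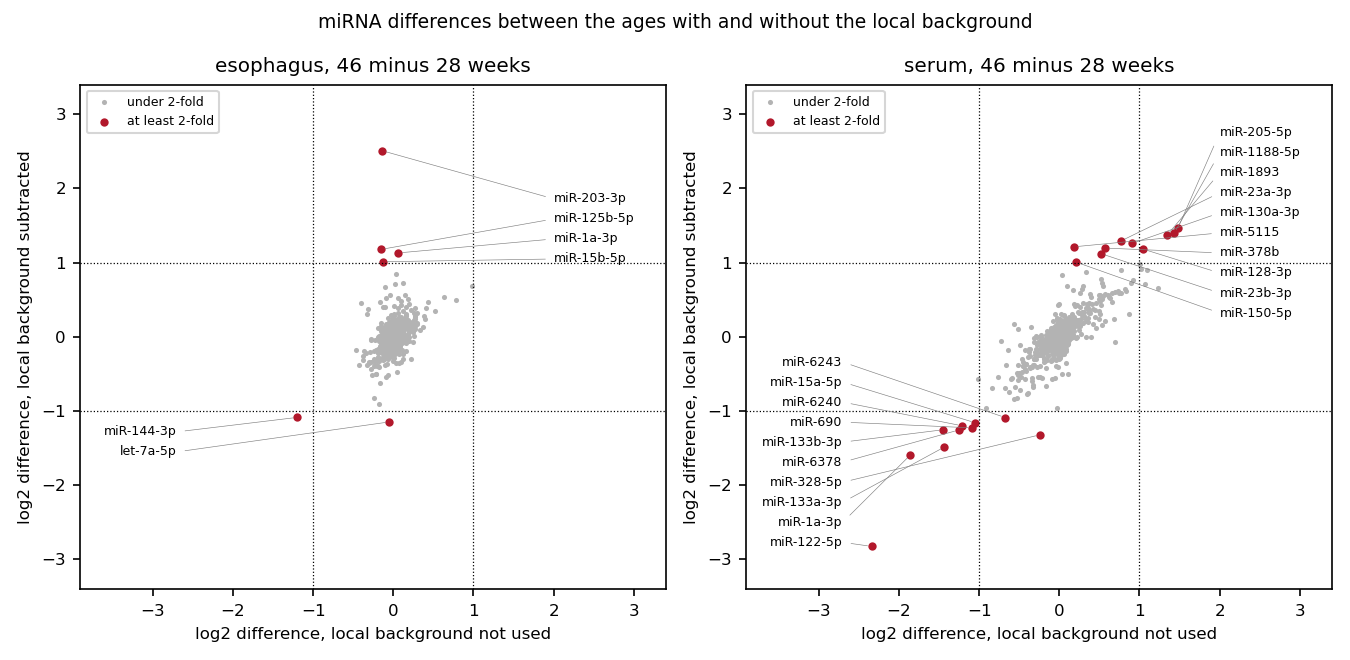
Each point is a miRNA detected at both ages, in esophagus (left) and serum (right), with its log2 difference of 46 minus 28 weeks without the local background on the x axis and with it subtracted on the y axis. Dotted lines mark 2-fold, red points passed 2-fold with the local background subtracted, and miR-203-3p in esophagus lies at 2.51 on the y axis and -0.14 on the x axis.

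In serum, the striated muscle miRNAs and the liver miRNA miR-122-5p fell between 28 and 46 weeks. The miRNA miR-122-5p, which makes up most of the miRNA of hepatocytes, had a log2 difference of -2.82 (spot-noise SD 0.11), and its spot intensity went from 637 to 123. The striated muscle miRNAs miR-1a-3p, miR-133a-3p and miR-133b-3p fell by 1.60, 1.49 and 1.25 on the log2 scale (spot-noise SD 0.09, 0.09 and 0.10). The squamous miRNA miR-205-5p rose by 1.46 (spot-noise SD 0.07), with spot intensities of 81.6 and 232. All 5 of these differences stayed past 2-fold without the local background.

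Of 822 miRNAs detected in serum at both ages, 10 were at least 2-fold higher at 46 weeks and 10 at least 2-fold lower. The other higher ones were miR-1188-5p at 1.40, miR-1893 at 1.37, miR-23a-3p at 1.29, miR-130a-3p at 1.26, miR-5115 at 1.21, miR-378b at 1.196, miR-128-3p at 1.18, miR-23b-3p at 1.12 and the lymphocyte miRNA miR-150-5p at 1.01. The other lower ones were miR-328-5p at -1.32, miR-6378 at -1.26, miR-690 at -1.23, miR-6240 at -1.199, miR-15a-5p at -1.16 and miR-6243 at -1.09. Of the 10 increases, 4 were kept without the local background (miR-205-5p, miR-1188-5p, miR-1893 and miR-128-3p) and 8 of the 10 decreases, all but miR-328-5p at -0.24 and miR-6243 at -0.67. The spots of miR-5115 read 4270 and 4266 and those of miR-150-5p 496.2 and 501.9, and without the local background their differences were 0.18 and 0.21, and both stood at -0.13 in the authors' table.

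The balance of higher and lower serum miRNAs depended on how the arrays were scaled. The authors' deposited value table gave 28 higher and 74 lower with a median over all miRNAs of -0.25, and subtraction of the BLANK mean with quantile normalization gave 16 and 109 with a median of -0.41. With subtraction of the BLANK mean and scaling to the median the counts were 64 and 32, and with scaling to the median alone 8 and 12. Relative to any of these medians, miR-122-5p, miR-1a-3p, miR-133a-3p and miR-133b-3p were lower and miR-205-5p was higher at 46 weeks. The spike-in spots averaged 9324 net units on the serum array at 28 weeks and 14018 at 46 weeks.

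All 3 detected striated muscle miRNAs fell at least 2-fold in serum, and their median was -1.49, at the 0.185th percentile of random lists (-1.45 without the local background), while miR-206-3p was detected at 28 weeks only. The hepatocyte list held miR-122-5p alone. The squamous pair had a median of 1.03, at the 99.985th percentile (1.08 without the local background), with miR-205-5p past 2-fold and miR-203-3p at 0.60. The epithelial miR-200 family, also of epithelial origin, had a median of 0.00 (45.8th percentile), and its members were dim in serum, with spot intensities of 51.7 to 61.5 at 28 weeks. The columnar and glandular list had a median of -0.02 (47.9th percentile), and of -0.29 (1.65th percentile) without the local background. Among 8 inflammation and leukocyte miRNAs, miR-150-5p passed 2-fold and the median was 0.34 (97.52nd percentile), with miR-146a-5p at 0.88, miR-223-3p of myeloid cells at 0.65 and miR-21a-5p at 0.32. Without the local background the median was 0.31 (98.8th percentile) and miR-223-3p, at 1.23, passed 2-fold.

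None of the 5 erythrocyte miRNAs passed 2-fold in serum, although miR-144-3p and miR-144-5p passed it in the authors' table, at -1.63 and -1.59. Their median was -0.68 (0.12th percentile), with miR-451a at -0.68, miR-16-5p at -0.75, miR-144-3p at -0.69, miR-144-5p at -0.10 and miR-486-5p at 0.00. Without the local background the median was -0.32 (2.80th percentile). In serum 31 miRNAs were detected at 46 weeks only and 178 at 28 weeks only. The brightest had net signals of 19.7, 5.08 and 4.73 for miR-5624-5p, miR-669o-5p and miR-291a-3p at 46 weeks, and 17.3, 12.7 and 11.3 for miR-5121, miR-122-3p and miR-376b-3p at 28 weeks. In the authors' table the log2 difference was 1.14 for miR-669o-5p, 1.31 for miR-291a-3p, -2.68 for miR-5121 and -2.12 for miR-376b-3p. Each of these sets a detected spot against one under the detection limit used here, so their sizes are not reliable.

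**Figure D2:**
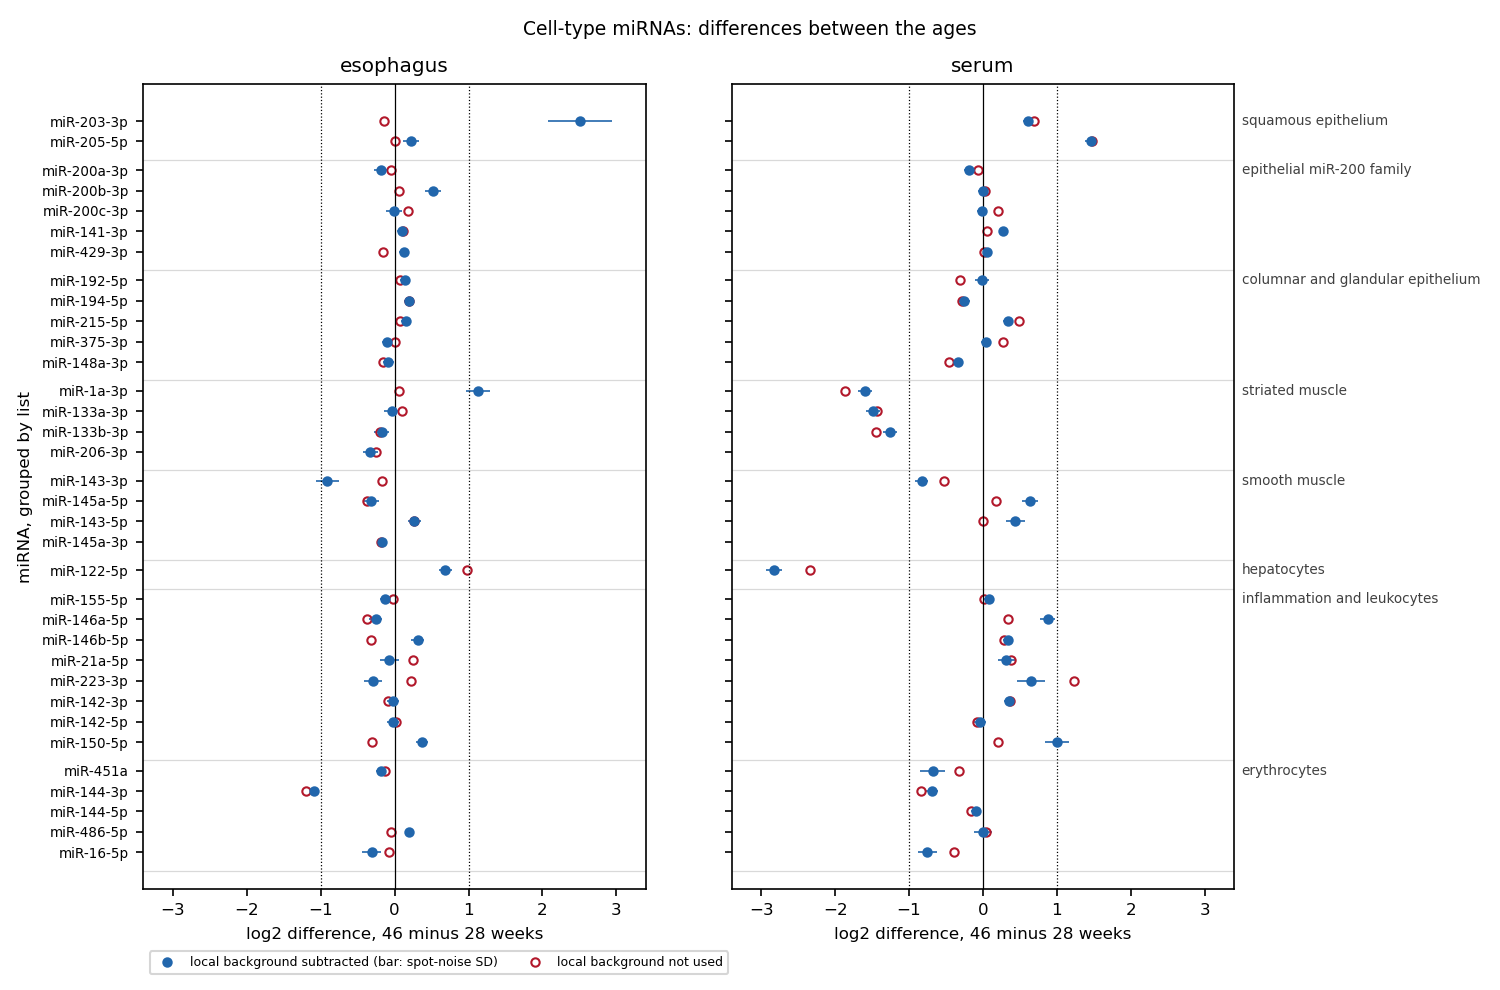
Log2 differences of 46 minus 28 weeks (x axis) for cell-type miRNAs grouped by list (y axis), in esophagus (left) and serum (right), with the local background subtracted (filled points, bars are the spot-noise SD) and without it (open points). Dotted lines mark 2-fold, only miRNAs detected at both ages are drawn, and in serum miR-122-5p lies at -2.82 and miR-205-5p at 1.46.

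The design of the series counts 20 miRNAs higher and 44 lower at 46 weeks in both esophagus and serum, with no threshold stated. At 2-fold, no miRNA was higher in both and none was lower in both among the 731 detected on all arrays, where independent lists of these sizes would share 0.055 and 0.027. Across these miRNAs the differences in esophagus and serum had a Pearson correlation of 0.11, or -0.15 without the local background, and 50.8% had the same sign. At 1.5-fold, miR-203-3p, miR-125b-5p and miR-5115 were higher in both and miR-144-3p, miR-143-3p and let-7a-5p lower in both, against 0.43 and 0.14 for independent lists. These 6 were named after their values were seen. Without the local background, miR-144-3p was the one of the 6 to pass 1.5-fold in both, at -1.19 in esophagus and -0.84 in serum.

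In the authors' deposited value table, miR-144-3p was the one miRNA at least 2-fold lower in both sample types, with values of 198.4 and 16.5 in esophagus at 28 and 46 weeks and 315.2 and 101.9 in serum, and no miRNA was at least 2-fold higher in both. The table held 7 miRNAs higher and 15 lower in both at 1.5-fold and 31 and 100 at 1.2-fold. The counts of 20 and 44 in the design lie between those at 1.5-fold and at 1.2-fold. Among those at 1.5-fold, named after their values were seen, miR-128-3p, miR-130b-3p and miR-21a-3p were higher, at 0.71, 1.40 and 1.17 in esophagus and 1.39, 0.67 and 0.89 in serum. Several of these values lay near background, so the sizes are not reliable. In esophagus at 28 weeks the table gave 24.2, 16.2 and 16.5, under the median of 25. For miR-21a-3p it gave 5.9 and 10.9 in serum at 28 and 46 weeks. In the main setting miR-128-3p stood at 0.17 in esophagus.

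Of list members detected on all arrays, 3 of 3 striated muscle and 2 of 3 smooth muscle miRNAs were at least 4-fold higher in esophagus than in serum at both ages, and 2 of 4 erythrocyte miRNAs at least 4-fold higher in serum. The smooth muscle strand miR-143-5p stood at 0.07 and -0.15, and the erythrocyte miRNA miR-144-3p at -0.29 and -0.66. At 28 and 46 weeks the log2 difference of esophagus minus serum was 4.97 and 4.49 for the smooth muscle miRNA miR-143-3p, 4.15 and 2.95 for its cluster partner miR-145a-5p, 3.27 and 4.68 for miR-133a-3p and 3.28 and 4.32 for miR-133b-3p. In the opposite direction it was -7.64 and -6.48 for miR-451a, -3.899 and -3.67 for the probe of the erythrocyte miRNA miR-486-5p and -3.09 and -2.38 for miR-25-3p.

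In all, 13 miRNAs were at least 4-fold higher in esophagus at both ages and 10 at least 4-fold higher in serum. The named ones also included miR-690 (4.42 and 5.46), miR-1902 (3.49 and 3.20), miR-6412 (3.60 and 3.16) and miR-5097 (2.44 and 2.32) on the esophageal side. On the serum side they included miR-1298-5p (-3.91 and -3.76), miR-711 (-2.78 and -3.28), miR-5122 (-2.62 and -2.52), miR-15b-5p (-4.12 and -2.48) and miR-1893 (-2.34 and -2.98). List members among the 13 were also miR-1a-3p (2.04 and 5.34) and miR-205-5p (3.54 and 2.26), while miR-203-3p stood at 1.38 and 3.15. The values at 28 weeks of miR-203-3p, miR-1a-3p and miR-15b-5p carry a raised local background in esophagus. Without it miR-203-3p stood at 4.89 and 3.97, miR-1a-3p at 3.9988 and 5.97 and miR-15b-5p at -3.05 and -2.11 at 28 and 46 weeks. Over 731 miRNAs the differences at the 2 ages had a Pearson correlation of 0.89. With the BLANK mean subtracted the counts were 41 and 28, and the authors' table gave 36 and 32. With the BLANK mean subtracted and scaling to the median, miR-5097 at 1.74 and 1.93 and miR-1893 at -1.94 and -3.47 no longer passed 4-fold at both ages. The kits used for tissue and serum differed.

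**Figure D3:**
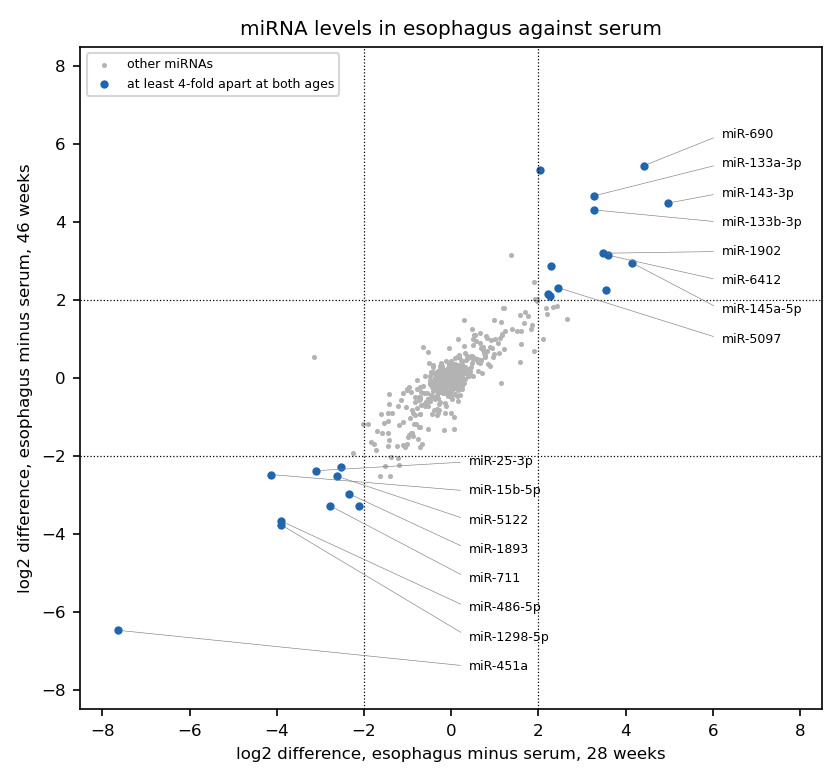
Each point is 1 of the 731 miRNAs detected on all 4 arrays, with its log2 difference of esophagus minus serum at 28 weeks on the x axis and at 46 weeks on the y axis. Dotted lines mark 4-fold, blue points passed it at both ages (13 higher in esophagus, 10 higher in serum), and miR-451a lies at -7.64 and -6.48.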

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

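The tests of RNA amount and of erythrocyte RNA in this part were chosen only after the serum values were seen.

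The liver miRNA miR-122-5p and the striated muscle miRNA miR-1a-3p had differences of opposite sign in esophagus and serum. The log2 difference of 46 minus 28 weeks was 0.69 in esophagus and -2.82 in serum for miR-122-5p, and 1.13 in esophagus and -1.60 in serum for miR-1a-3p. The difference between the sample types was not tested. For miR-1a-3p the esophageal value was 0.06 without the local background and -0.013 in the authors' table, so the size of the esophageal difference rested on the local background, and its sign turned in the authors' table, while for miR-122-5p it was 0.98 without the local background and 2.11 in the authors' table.

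The 4 detected striated muscle and hepatocyte miRNAs fell in serum. Less serum RNA or weaker labelling at 46 weeks would lower all bright miRNAs alike. On the scale of the spike-in spots the median of 256 bright serum miRNAs stood at -0.72 (MAD of single bright miRNAs 0.42). The median of these 4 was -2.51 relative to it, and the nearest member was at -1.99. The spike-in factor cancels in this difference. The 4 were taken up because they had fallen relative to other serum miRNAs, so the contrast was set by that choice and is no test of this explanation. More erythrocyte RNA in the serum at 28 weeks would lower erythrocyte miRNAs at least as much. With the BLANK mean subtracted and scaling to the median, the median of the 4 was -2.45 and that of 5 erythrocyte miRNAs -0.46, a difference of -1.99. The erythrocyte miRNAs were split, with miR-144-3p at -1.32, miR-144-5p at -1.29, miR-451a at -0.46, miR-16-5p at -0.44 and miR-486-5p at 0.32. The 4 fell further than each of these, but they were taken up for their fall, which largely set this contrast. A change with age in what muscle and liver release may be a candidate explanation, open and untested like differences between mice or blood draws, because each age had 1 array.

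Some spots that the comparisons leave out, named S-Probe, had a signal of at least 2 times the limit set by spots without probe, which was 63.1 and 64.0 in esophagus and 51.1 and 60.3 in serum at 28 and 46 weeks. What these spots detect was not given in the sources used here. In esophagus at 28 and 46 weeks the spot intensity was 175 and 178 for S-Probe1002, 4201 and 4939.7 for S-Probe1014, 198 and 187 for S-Probe1016, 1207 and 1139.8 for S-Probe1018, and 200.5 and 198 for S-Probe1019. In serum it was 200.3 and 258 for S-Probe1007 and 143.9 and 127.5 for S-Probe1014.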

How the results depend on the processing

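The settings normexp without local background, subtraction of the BLANK mean with scaling to the median, and detection above the No Probe limit were chosen after seeing the data. Over all settings, 25 of 748 values other than counts were called differences or list medians that changed sign, and medians of uncalled lists near 0 also took either sign, such as the esophageal miR-17-92 median at -0.15 as reported and 0.05 without the local background. A further 287 values moved without being counted as reversed, and 436 were counted as the same. Those that moved ranged from 0 of 74 above the No Probe limit to 57 of 75 with the BLANK mean subtracted and quantile normalization. The serum decreases of miR-122-5p and the 3 striated muscle miRNAs and the serum increase of miR-205-5p kept their direction and stayed past 2-fold in values under each setting, and at the 3-fold threshold miR-122-5p and miR-1a-3p passed. The squamous median in serum ranged from 0.99 to 2.22 and the striated muscle median from -2.44 to -0.70, the latter without a detection filter, which adds members near background. Counts are given as higher and lower at 46 weeks, with 4 and 2 in esophagus, 10 and 10 in serum, 0 and 0 in both, and 13 and 10 for higher in esophagus and higher in serum as reported. Among lists with at least 2 detected members, in esophagus 2 list medians fell in the lowest 2.5% of random lists and 1 in the highest 2.5%, and in serum 3 and 3.

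With scaling to the median, esophagus had 1 lower miRNA, 1 list in the lowest 2.5% and 2 in the highest. With the BLANK mean subtracted and quantile normalization, the counts were 12 and 14 in esophagus, 16 and 109 in serum, 1 lower in both, and 41 and 28 between sample types, with 1 esophageal list in the lowest 2.5%. Values that reversed were the esophageal squamous median at -0.15, esophageal miR-203-3p at -0.17, miR-125b-5p at -0.24 and miR-15b-5p at -0.35, the serum median of the Sfmbt2 cluster families at -0.18, and serum miR-5115 at -0.062 and miR-150-5p at -0.13. With an offset of 16, serum had 16 lower miRNAs, 1 miRNA was higher in both, 23 were higher in esophagus than serum, and 1 esophageal list was in the lowest 2.5%. With the authors' value table the counts were 11 and 13 in esophagus, 28 and 74 in serum, 1 lower in both, and 36 and 32 between sample types. Reversed were the esophageal squamous median at -0.096, miR-203-3p at -0.011, miR-125b-5p at -0.16, miR-1a-3p at -0.013 and miR-15b-5p at -0.20, the serum Sfmbt2 median at -0.010, and serum miR-5115 at -0.13 and miR-150-5p at -0.13.

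Without a detection filter esophagus had 1 list in the lowest 2.5% and 2 in the highest. With the brighter miRNAs only, 2 esophageal lists and 1 serum list were in the highest 2.5%. At 1.5-fold (2-fold between sample types) the counts were 9 and 5 in esophagus, 35 and 25 in serum, 3 and 3 in both, and 40 and 36 between sample types. At 3-fold (8-fold) they were 1 and 0 in esophagus, 0 and 2 in serum, and 6 and 3 between sample types. The threshold itself sets these counts.

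Without the local background esophagus had 0 higher and 1 lower miRNA and 1 list in the lowest 2.5%, and reversed values were the squamous median at -0.0695, miR-203-3p at -0.14, miR-125b-5p at -0.16 and miR-15b-5p at -0.13. With the BLANK mean subtracted and scaling to the median, the counts were 12 and 13 in esophagus, 64 and 32 in serum, 3 and 1 in both, and 39 and 26 between sample types, with 2 esophageal lists in the highest 2.5%. Reversed there were the squamous median at -0.088, miR-203-3p at -0.0034, miR-125b-5p at -0.16, miR-1a-3p at -0.0054 and miR-15b-5p at -0.19, all in esophagus. Above the No Probe limit 2 esophageal lists were in the highest 2.5%, and the serum Sfmbt2 median reversed to -0.0017. The esophageal lists in the lowest or highest 2.5% as reported were erythrocytes, let-7 and squamous epithelium. None of them kept that place without the local background, at percentiles 10.5, 7.37 and 34.1. The list in the lowest 2.5% there was smooth muscle. With the BLANK mean subtracted and scaling to the median, none kept it either, at percentiles 9.85, 7.055 and 32.995. The esophageal reversals occur in settings that leave out the local background. For the other changes the cause was not tested.

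Averaging against each spot set alone was not run, because every miRNA probe is spotted at 1 place. No paired analysis was possible because each group had 1 array and the labels number no mice. The BLANK-subtracted values give no value for undetected miRNAs. The authors' table left out some of these but listed 89 and 96 of them in esophagus at 28 and 46 weeks and 68 and 90 in serum. Signal over background limits dim miRNAs, whose differences the offset draws toward 0.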

Other observations

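The tests of local background, of blood in the tissue and of scaling were chosen only after the results were seen, and the test of carried-over epithelial cells was chosen before.

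In the let-7, miR-17-92, miR-34 and miR-30 families, let-7a-5p in esophagus was the one member past 2-fold, and it stood at -0.05 without the local background. With the BLANK mean subtracted and scaling to the median, which does not draw dim miRNAs toward 0, miR-92a-3p at 1.05 and miR-106b-5p at -1.0005 passed 2-fold in serum. In the miR-17-92 and paralogous clusters, which drive proliferation, the median over 12 esophageal members was -0.15 (4.24th percentile) and 0.05 without the local background, and over 13 serum members -0.13 (12.2nd percentile), with miR-106b-5p at -0.96 and miR-92a-3p at 0.76 in serum. The let-7 family, which restrains proliferation, had a serum median of -0.17 (10.5th percentile), with let-7a-5p at -0.66 and let-7f-5p at 0.32, and 0.05 with the BLANK mean subtracted and scaling to the median. The miR-30 family, with 5 members detected in each, stood at -0.21 (12.8th percentile) in esophagus, or -0.28 (0.835th percentile) with the BLANK mean subtracted and scaling to the median, and at 0.22 (77.0th percentile) in serum. In the miR-34 and miR-449 family of ciliated and stressed cells, miR-34a-5p alone was detected at both ages in esophagus, at 0.08 (66.7th percentile), and the 2 serum members had a median of 0.03 (71.8th percentile). Of 15 detected miRNAs reported in Barrett progression, miR-205-5p alone passed 2-fold in serum and the median was 0.0065 (65.3rd percentile). It was 0.085 (94.2nd percentile) without the local background and 0.37 (98.6th percentile) with the BLANK mean subtracted and scaling to the median, where miR-203-3p at 1.92, miR-215-5p at 1.42 and miR-375-3p at 1.16 also passed 2-fold, as did miR-106b-5p in the opposite direction.

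Among other cell types, the 6 fibroblast and stroma miRNAs had a median of -0.15 (16.5th percentile) in esophagus, or -0.24 (0.97th percentile) with the BLANK mean subtracted and scaling to the median, and -0.08 (27.9th percentile) in serum, where miR-29c-3p stood at -0.84 and miR-214-3p at 0.29, and none passed 2-fold. The 2 endothelial strands of miR-126 had medians of -0.17 (19.1st percentile) and 0.14 (68.3rd percentile). Of 4 neuronal miRNAs, miR-128-3p alone was detected at both ages, at 0.17 (94.9th percentile) in esophagus and past 2-fold at 1.18 (97.0th percentile) in serum. None of the 3 pancreatic acinar miRNAs was detected at both ages in esophagus or serum. The 4 detected striated muscle miRNAs of esophagus had a median of -0.11 (31.5th percentile), with miR-206-3p at -0.33 and 1 member, miR-1a-3p, past 2-fold. In serum the smooth muscle median over 3 members was 0.44 (89.9th percentile) and 0.00 without the local background, with miR-145a-5p at 0.63 and miR-143-3p at -0.83. The hepatocyte miRNA miR-122-5p lay at the 98.1st percentile in esophagus and the 0.565th in serum.

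The Dlk1-Dio3 imprinted cluster had a median of 0.03 (80.7th percentile) over 28 esophageal members and -0.03 (14.2nd percentile) over 19 serum members, with miR-370-3p at -0.48 and miR-493-3p at 0.32 in serum and none past 2-fold. Its percentiles were 97.1 and 1.495 without the local background, with medians of 0.03 and -0.04, and 97.7 and 3.23 with the BLANK mean subtracted and scaling to the median, with medians of 0.15 and -0.24. On this last scale 5 serum members passed 2-fold, namely miR-487b-3p at 1.75, miR-493-3p at 1.196, miR-666-5p at 1.17, miR-329-3p at -1.07 and miR-434-3p at -1.04, chosen after their values were seen. Some lay near the floor, where the No Probe limits in serum were 51.1 and 60.3 at 28 and 46 weeks. The spot of miR-487b-3p read 50.7 at 28 weeks, and those of miR-329-3p and miR-434-3p read 57.3 and 56.3 at 46 weeks. The Sfmbt2 cluster families had 39 detected members in each, none past 2-fold, with medians of 0.0078 (65.6th percentile) and 0.04 (99.5th percentile). The serum median was 0.29 with the BLANK mean subtracted and scaling to the median, and it turned to -0.18 with the BLANK mean subtracted and quantile normalization, -0.010 in the authors' table and -0.0017 above the No Probe limit. On the first of these scales members passed 2-fold, among them miR-466q at 1.22 and miR-467a-5p at 1.15 in serum and miR-669f-3p at -1.33 and miR-466c-5p at 1.17 in esophagus. The serum spots of miR-466q read 49.6 and 59.7 at 28 and 46 weeks, under the No Probe limit at both ages. Names numbered 1000 or more had medians of 0.01 (96.8th percentile) over 314 esophageal members, none past 2-fold, and -0.013 (1.85th percentile) over 313 serum members, of which 3 rose and 3 fell. Without the local background these percentiles were 98.4 and 0.01. These names made up 35.7% of probes and took between 68.1% and 71.4% of the net signal of an array.

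In esophagus, 1 of the 6 miRNAs at least 2-fold apart between the ages, miR-144-3p, stayed so without the local background, so uneven local background readings may account for the other 5. Less blood in the tissue would lower miR-451a with miR-144-3p, but with the BLANK mean subtracted and scaling to the median the esophageal difference of miR-451a was -0.22 (spot-noise SD 0.10) against -3.59 for miR-144-3p, which argues against blood as the whole cause. The size of the -3.59 is not reliable, because the miR-144-3p spot at 46 weeks lay near background. Without the local background miR-451a stood at -0.13 and miR-144-3p at -1.19. Age stays open and untested, and each miRNA was read from a single spot.

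In serum, the squamous miRNAs miR-205-5p and miR-203-3p were higher at 46 weeks under each of 8 settings, the reported one included. The smaller offset, normexp without the local background, and BLANK subtraction with quantile normalization changed the background or offset only. These do not test the scaling. Among settings that changed the scaling, the lowest difference of either was 0.56, for miR-203-3p with quantile normalization over the other sets of arrays. With scaling to the median, miR-203-3p stood at 0.61 and miR-205-5p at 1.37. Each of these scalings is set by the bulk of serum miRNAs, and the pair was taken up because it rose relative to that bulk. The values show that this relative rise does not depend on which of them is used. They cannot decide whether the scaling between the arrays is the cause. Epithelial cells carried over in the blood draw would also bring the miR-200 family, whose 5 detected members had a median of 0.11 with the BLANK mean subtracted and scaling to the median. That origin and a release of squamous miRNAs with age cannot be told apart, because the miR-200 members lie close to background in serum. Shedding from the diseased esophagus may be a candidate explanation. It was not tested.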
